A study of Mus musculus with 4 samples.

How the data were processed

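Chromatin immunoprecipitation followed by sequencing was used to map BCL6, a zinc finger transcriptional repressor, in adipocyte nuclei of C57BL/6 mice. The mice carried Adipoq-Cre with a Cre-dependent Sun1-sfGFP-myc tag. The Cre is expressed in adipocytes, so that their nuclear membranes carry the tag. Per the labels' protocols, inguinal (subcutaneous) and perigonadal (visceral) fat was minced and fixed with disuccinimidyl glutarate for 30 minutes and then with 1% formaldehyde for 10 minutes. Tagged nuclei were pulled out of the homogenate with beads against the myc epitope, and their sheared chromatin was precipitated with a custom guinea pig polyclonal antibody against mouse Bcl6. Each of the 2 depots had 1 BCL6 library and 1 input library, 4 samples in all. The analysis used the peak lists of the 2 BCL6 libraries; the 2 input libraries were not analysed here.

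Reads were processed with Bowtie 1.2 and HOMER on the mm10 mouse genome, per the submitters' processing notes. The lists are HOMER annotations of peaks on mm10, per the file headers. The header of the inguinal list names a false discovery rate of 0.001 for its peaks and the header of the perigonadal list names no threshold, so the depots may have been called at different limits. No pooling of libraries is stated in the sources used here. The deposited score of each peak is the authors' value and was used to describe, rank or filter peaks within its own list. Across the lists scores served only to relate heights at shared sites, to order the shared pairs and to set a common minimum in an alternative, and no difference of level between depots was drawn from them. The scores within a list were whole multiples of a single step, 0.752 in the inguinal and 0.882 in the perigonadal list, for 100% of peaks within the rounding of the deposited values. A step was read as 1 sequenced tag after scaling for library size. The total that the caller scaled to is not given in the sources used here, so the depth of the libraries is unknown. The deposited focus ratio of each peak, a fraction from 0.5 to 0.979 that describes how tags lie around the peak centre, entered no comparison. The distance of each peak to the nearest annotated promoter and the annotation of its position are also the authors' values. Because each depot had a single library, no test between depots was possible and no p-value is given.

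Overlap of at least 1 bp made a peak shared. Shares carry Wilson 95% intervals, and scores carry exact Poisson 95% intervals of their tags. Both cover counting error only, because reads without molecular identifiers are not independent molecules and because no second animal or library entered. Overlap was set beside 1000 random placements of the peaks on their own chromosomes and beside 1000 shifts of each peak by 10 to 50 kb. Each list was also ranked by score and split into 4 equal parts. Gene names and types came from a RefSeq gene table of GRCm38.p6, whose chromosomes are those of mm10. Genes were matched by Entrez number, which also restored names that a spreadsheet had turned into dates. Of the inguinal list's 1593 nearest genes 1589 matched, and of the perigonadal list's 3180 genes 3178 matched. A gene counted as having a peak if it is protein-coding and the authors' nearest promoter lay within 50 kb. This departs from the planned rule of the nearest protein-coding start site, since the gene table gives no strand. The nearest promoter belonged to no protein-coding gene for 15.5% of inguinal and 15.6% of perigonadal peaks, which were assigned to none.

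Before the data were examined, 19 gene lists with 313 entries were fixed, for adipocyte functions, known BCL6 biology, depot identity and the other cell types of fat. For each list and depot the number of members with a peak was set beside 10000 random lists of protein-coding genes of the same size. These were matched on decile of the gene's territory, which is its length plus the gaps to the midpoints toward its neighbours. This replaced the planned distance between start sites. A list that exceeded at least 97.5% of random lists is reported as past that limit, as a description of these libraries. Counts of so few genes move in whole steps, so the chance of passing was taken from the random lists themselves. Over the 38 list and depot pairs it sums to 0.461 lists.

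The rule for named genes, also fixed beforehand, took the 10 shared pairs with the highest lower score of the pair, the 8 tallest peaks without a partner in each list, up to 4 members of each gene list with the tallest peaks, and Bcl6 itself. Peaks without an assigned gene are given by position. A few items that the rule or a list's count takes in are not reported here by name. Other genes named below complete the count of a list or were chosen after their values were seen. Alternatives covered the overlap rule, list length, a common minimum score, autosomes, the promoter window, the assignment distance and the matching of random lists. Limits on tags, repeats, shared peaks, gene ends and protein-coding promoters were added after the data were seen. The gene ends alternative counted every protein-coding gene with an end within 50 kb of a peak centre or spanning it. Alternatives by fold over input and the planned search for the BCL6 motif were not run, because the lists carry no fold and no genome sequence was used here.

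Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9. The procedures were tested on simulated data. All 300 planted shared peaks were recovered among 5741 simulated peaks with 0 others. The planted pairs were made to overlap and the others placed at random. This checks the computation and not the sharing of real peaks near the calling limit. Tag numbers were recovered for 100% of simulated scores in both lists. Of random lists of 20 genes, 0.5% passed the upper limit for the inguinal and 1.5% for the perigonadal peaks.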

Results

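BCL6 was mapped in adipocyte nuclei from inguinal and perigonadal fat of the same mouse line to find the genes it occupies in each depot. The inguinal list held 1785 peaks of 202 bp and the perigonadal list 3956 peaks of 184 bp. Peak scores ran from 6.77 to 200.1 with a median of 9.03 in the inguinal list. They ran from 5.29 to 260.1 with a median of 8.82 in the perigonadal list. Read as tags, the median peak rested on 12 tags in inguinal fat, with a Poisson 95% interval of 6.20 to 20.96, and on 10 tags in perigonadal fat, with an interval of 4.80 to 18.4. Peaks of up to 12 tags made up 58.7% of the inguinal and 76.0% of the perigonadal list. Without them, 738 and 950 peaks were left. Each depot was represented by 1 BCL6 library, so no difference between depots could be set against variation between animals.

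The first comparison asked which sites BCL6 occupied in both depots. The highest-scoring peak in each list lay on the promoter of Socs2, a growth hormone-induced inhibitor of cytokine signalling, at chromosome 10:95416811-95417013 in inguinal fat. Its score was 200.1 in the inguinal list (Poisson interval 176.8 to 225.6) and 260.1 in the perigonadal list (231.2 to 291.5). The promoter of Cish, another inhibitor of STAT5 signalling (chromosome 9:107296600-107296802), ranked 6 in each list, with scores of 65.4 and 85.5. The second-ranked peak of each list lay in intron 4 of 6 of Rnls, which encodes renalase, 117.7 kb from its promoter at chromosome 19:33274535-33274737, with scores of 88.0 and 133.1. Across the whole lists, 508 peaks were shared.

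Besides Socs2, Rnls and Cish, the top 10 shared sites lay at genes of varied function. The peak in the last intron of Ntpcr, a nucleoside triphosphatase gene, scored 82.7 in inguinal and 104.9 in perigonadal fat (chromosome 8:125747515-125747717). An intergenic peak 38.8 kb upstream of Ahctf1, which encodes a nuclear pore protein, scored 79.7 and 106.7 (chromosome 1:179842676-179842878). A peak 3.86 kb upstream of Zfp292, a zinc finger gene, scored 60.9 and 74.1. The promoter of Wrnip1, which encodes a partner of the Werner helicase, scored 71.5 and 60.8. Intron 1 of Arid3b, a DNA-binding protein gene, scored 54.9 and 55.5. The site 1.24 kb upstream of Atp5g1, a gene for subunit c of ATP synthase, scored 54.2 and 60.8 and lies in an annotated LINE repeat.

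The 508 shared peaks were 28.5% of the inguinal list (Wilson 95% interval 26.4 to 30.6%) and 12.8% of the perigonadal list (11.8 to 13.9%). Random placement of the inguinal peaks gave a mean of 1.12 shared peaks and at most 5 in 1000 draws, and shifts of 10 to 50 kb a mean of 1.93 and at most 8. Sharing followed peak height. In the tallest of 4 equal parts of the inguinal list 77.1% of peaks were shared (73.0 to 80.8%), and in the next parts 25.8%, 6.05% and 4.92%. The matching shares of the perigonadal list were 42.2% (39.1 to 45.3%), 4.85%, 2.22% and 2.12%. All of the 10 tallest peaks of either list were shared, as were 49 of the 50 tallest. With peaks of more than 12 tags alone, a limit chosen after the data were seen, 51.2% of inguinal and 39.8% of perigonadal peaks were shared. With both lists held to 1785 peaks the share was 25.9% from either side.

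**Figure D1:**
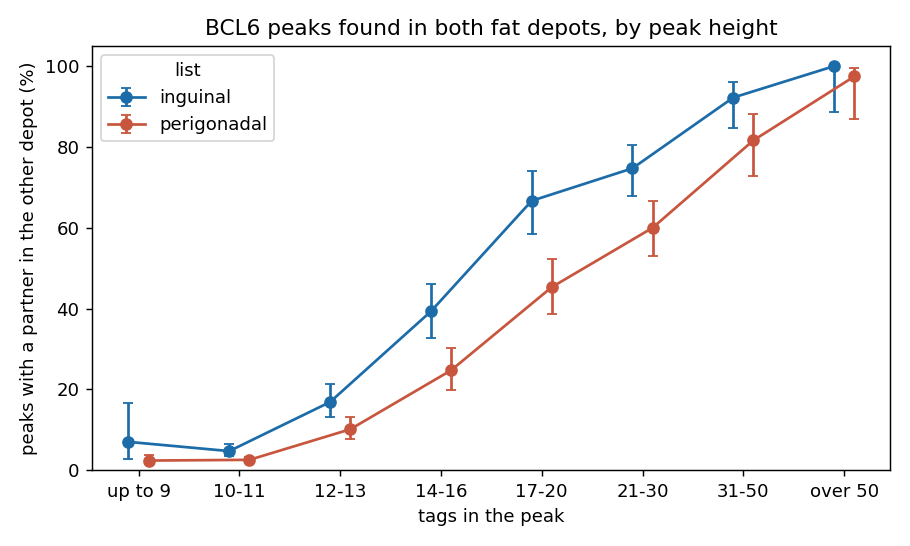
Share of BCL6 peaks with an overlapping peak in the other depot (y axis, percent) by the number of tags in the peak (x axis), for the inguinal and the perigonadal list. Points are shares and bars Wilson 95% intervals; the share rises from 4.74% of inguinal and 2.57% of perigonadal peaks of 10 to 11 tags to 100% and 97.4% of peaks of over 50 tags.

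At the 508 shared sites the scores of the depots rose together. Across sites, Pearson's r of the log2 scores was 0.76 and Spearman's rho 0.68. Sites are not independent replicates, so no p-value is attached. Of the 50 tallest peaks of each list, 35 pairs were common to both. The scores are scaled within each list, so they give no direction between depots.

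**Figure D2:**
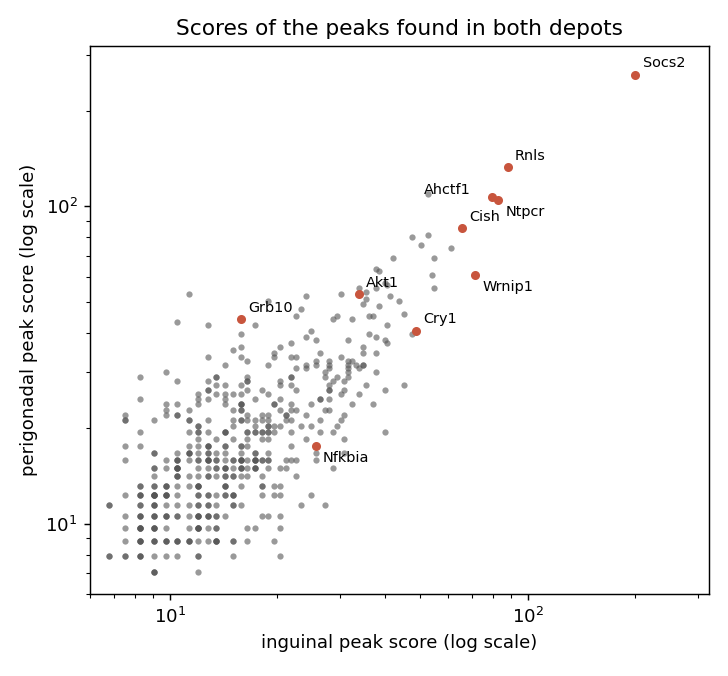
Score of each of the 508 shared peaks in the inguinal list (x axis, log scale) and in the perigonadal list (y axis, log scale), each point being a site and the labelled ones named in the text. Scores rise together, with r of 0.76 on the log2 scale, and Socs2 stands at the top of both lists with 200.1 and 260.1.

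The tallest peaks found in a single depot were lower than the tallest shared ones. In the inguinal list these were led by a peak in the intron of Cldn34d, a claudin-like gene, at chromosome X:76598949-76599151 with a score of 37.6. This peak lies in a satellite repeat. The following ones scored from 24.8 to 22.6. They lay in intron 1 of Zfhx4 (chromosome 3:5235576-5235778), intron 1 of Pde3a (chromosome 6:141333298-141333500) and intron 1 of Ell, an elongation factor gene. Others lay in intron 18 of Ctr9, a gene of the PAF1 complex, 30.2 kb from Ddit4, an inhibitor of mTORC1, 46.9 kb from Vmn1r3, and at chromosome 13:37440739-37440941, 95.5 kb from Ly86.

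In the perigonadal list the tallest unshared peak scored 45.0 and lay in intron 2 of the non-coding gene D030024E09Rik at chromosome 15:61753953-61754137. Peaks 9.85 kb upstream of Bnip3, a mitophagy receptor gene, in intron 2 of Hdac4, a class IIa histone deacetylase gene, and on the promoter of Slc39a10, a zinc transporter gene, scored 36.1 each. Peaks near Sfxn3, in the non-coding gene Gm31763 (chromosome 10:67025773-67025957), in exon 2 of Commd5 and on the promoter of Zfp113 scored 35.3, 34.4, 34.4 and 32.6. Among peaks of more than 30 tags, 7 of 120 inguinal and 19 of 137 perigonadal peaks had no partner. A missing partner means that no peak was called, not that BCL6 was absent.

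The second comparison asked where the peaks lie relative to genes. In both depots most sites were intronic or intergenic: introns held 47.0% of inguinal and 47.1% of perigonadal peaks, and intergenic positions 43.5% and 42.9%. Within 1 kb of an annotated promoter lay 126 inguinal peaks, 7.06% of the list (Wilson interval 5.96 to 8.34%), and 246 perigonadal peaks, 6.22% (5.51 to 7.01%). The intervals of the depots overlap. Counted against either end of a protein-coding gene, because the strand of the genes was not used here, 7.62% of inguinal and 7.46% of perigonadal peaks lay within 1 kb. Random placement gave 3.07% and 3.11%. Within 5 kb of a promoter lay 16.6% and 17.3% of peaks.

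Of 21887 protein-coding genes, 931 had an inguinal and 1946 a perigonadal peak within 50 kb, and 394 had both. Independent lists of these sizes would have 82.8 genes in common, a number that is not matched on the territory of the genes. A shared peak was assigned to 286 genes. With 10 kb in place of 50 kb the numbers were 396 and 872, and with both lists held to 1785 peaks the perigonadal number was 958. Bcl6 itself had a peak 23.6 kb upstream of its promoter in inguinal fat with a score of 10.5 (chromosome 16:24012132-24012334). Inguinal peaks farther upstream, at 88.7, 140.2 and 177.9 kb, scored 11.3, 8.27 and 8.27. In perigonadal fat no peak lay within 50 kb, and those farther upstream, at 95.6 and 184.3 kb, scored 11.5 and 18.5. None of these peaks was shared.

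The third comparison asked which groups of genes have BCL6 peaks. Genes of growth hormone, IGF and STAT5 signalling had peaks in both depots, 7 of 18 in each. In addition to Socs2 and Cish, shared peaks lay 35.1 kb upstream of Ghr, the growth hormone receptor gene, with scores of 12.8 and 26.4, on the promoter of Igfals, which encodes a carrier of circulating IGF, with 9.03 and 14.1, and near Prlr, the prolactin receptor gene, with 17.3 and 15.0. Peaks near Socs3, a further cytokine signalling inhibitor, and Lepr, the leptin receptor gene, were found in perigonadal fat only, with 25.6 and 22.0. Those near Igf1 and Bcl6 were found in inguinal fat only, with 7.52 and 10.5. As many members were reached by 0 of 10000 matched random lists for inguinal and by 12 for perigonadal fat.

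Insulin signalling genes stood out in perigonadal fat, where 14 of 22 had a peak, a number reached by 0 of 10000 random lists with a median of 3. In inguinal fat 4 of 22 had one, more than in 95.4% of random lists, and 3 of 22 had a shared peak, more than in 99.2%. The tallest were in intron 2 of Akt1, the kinase downstream of the insulin receptor (chromosome 12:112671032-112671234), with 33.8 in inguinal and 52.9 in perigonadal fat, and in intron 1 of Grb10, an adaptor that restrains insulin receptor signalling, with 15.8 and 44.1. A peak 34.6 kb upstream of Insr, the insulin receptor gene, scored 13.5 and 15.9. Cblb, a ubiquitin ligase gene, had a perigonadal peak of 17.6 located 2.28 kb upstream, and Ptpn1, a phosphatase that dephosphorylates the insulin receptor, 1 of 15.9 in intron 1. Foxo1, Foxo3, Irs1, Irs2, Pdpk1, Pik3r1, Slc2a4 and Trib1 had low perigonadal peaks of 8.82 to 9.70. Trib1 also had an inguinal peak, of 7.52. With the perigonadal list held to 1785 peaks, 8 of 22 members had a peak, still past all random lists. With more than 12 tags 5 of 22 had one, more than in 99.95%. The difference between the depots' counts was not tested.

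Circadian clock genes had peaks for 7 of 18 members in perigonadal fat, more than in 99.9% of random lists, and for 2 of 18 in inguinal fat, more than in 77.8%. The tallest were in intron 1 of Cry1, a core clock repressor gene (chromosome 10:85183665-85183867), with 48.9 in inguinal and 40.6 in perigonadal fat. Perigonadal peaks 2.02 kb upstream of Per1, in the intron of Nfil3 and 1.58 kb upstream of Nr1d1, clock repressors as well, scored 27.3, 23.8 and 15.9. Those of Per2, Arntl and Rora scored 10.6, 9.70 and 8.82, and the other inguinal one, near Npas2, scored 9.03. Only Cry1 had a shared peak, which left the list within the random range (76.0%). So did counting every gene with an end within 50 kb of a peak or spanning one, at 8 of 18 members (93.5%).

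Inflammatory genes had an inguinal peak for 6 of 22 members, reached by 1 of 10000 random lists, and a perigonadal peak for 4 of 22, more than in 89.0%. Shared peaks lay in exon 3 of Nfkbia, the NF-kappaB inhibitor gene, with 25.6 and 17.6, on the promoter of Cxcl10, with 8.27 and 8.82, and 5.32 kb upstream of Cxcl5, with 9.03 and 8.82. Other inguinal peaks lay near Cxcl1, Irf1 and Lcn2. Only the Nfkbia peak rested on more than 12 tags in inguinal fat, and with that limit the list was within the random range (67.1%). Extracellular matrix genes had inguinal peaks for 4 of 20 members, more than in 98.2% of random lists, and perigonadal peaks for 5 of 20, more than in 93.8%, or 4 of 20 with more than 12 tags, more than in 99.7%. Shared peaks lay 45.2 kb downstream of the promoter of Sparc, a matrix glycoprotein gene, with 20.3 and 28.2, and 44.4 kb upstream of Col6a2, with 17.3 and 16.7. The one assigned to Col4a2, 41.7 kb upstream with 10.5 and 15.0, lies within Col4a1, another member of the list. Within 10 kb, only 1 inguinal member had a peak (66.3%).

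Adipocyte identity genes had peaks for 4 of 20 members in inguinal fat and 6 of 20 in perigonadal fat, more than in 98.7% and 99.1% of random lists. With both lists held to 1785 peaks the perigonadal count was 2 of 20, within the random range (75.8%). Only Klf15, a transcription factor gene induced during fat cell differentiation, had a shared peak, in intron 2 with scores of 14.3 and 15.0. Perigonadal peaks in Lpl, the lipoprotein lipase gene, and near Slc2a4, the insulin-responsive glucose transporter gene, scored 10.6 and 8.82. Lipogenesis genes had perigonadal peaks for 7 of 22 members, more than in 99.5%, and inguinal peaks for 2 of 22, more than in 71.1%. Within 10 kb the perigonadal count was 2 of 22, within the random range (76.0%). Elovl5, a fatty acid elongase gene, had a shared peak with 18.1 and 10.6. Acacb, an acetyl-CoA carboxylase gene, scored 12.3 in perigonadal fat, and Acsl1, an acyl-CoA synthetase gene, 11.3 in inguinal fat. Restricted to peaks of more than 12 tags, the identity list kept 1 of 20 members in either depot and the perigonadal lipogenesis list 1 of 22, all within the random range.

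Genes that BCL6 is known to regulate in B cells and T follicular helper cells had inguinal peaks for 4 of 20 members, more than in 98.5%, and perigonadal peaks for 3 of 20, more than in 65.1%. Shared peaks lay on the promoter of Ccnd2, the cyclin D2 gene, with 10.5 and 10.6, and 1.71 kb upstream of Myc, with 9.03 and 13.2. The others were Bcl2 and Gpr183 in inguinal fat and Irf4 in perigonadal fat. With peaks of more than 12 tags alone the inguinal list was within the random range (64.3%).

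The remaining lists stayed under the limit in both depots. Of 16 lipolysis genes 0 had an inguinal and 1, Prkar2b, a perigonadal peak. Of 18 fatty acid oxidation genes 1, Ppargc1b, and 3, among them Cpt1a and Pdk4, had one, and of 16 thermogenic genes 0 and 2. Corepressor genes counted 0 and 3 of 16, led by Hdac4, whose 2 inguinal peaks, also intronic, lay beyond 50 kb, at 125.0 and 151.8 kb, with 9.03 and 9.78. Of these genes 9 of 16 had an end within 50 kb of a perigonadal peak or spanned one, more than in 98.8% of random lists. Inguinal developmental genes counted 0 and 1 of 10, and perigonadal developmental genes 1 and 3 of 10, with a shared peak 38.1 kb from Thbs1 scoring 38.4 and 48.5. Markers of other cell types had peaks at the level of matched random lists, whose medians were 0 or 1 for lists this short. In inguinal and perigonadal fat the counts were 0 and 2 of 13 for preadipocytes and fibroblasts, 0 and 0 of 14 for macrophages, 0 and 1 of 14 for lymphocytes, 0 and 0 of 12 for endothelium, and 1 and 1 of 12 for mammary and mesothelial epithelium. Over all lists, 10 of the 38 pairs of list and depot were past the limit. By chance 0.461 would be, from the share of each list's random lists that passed. The random lists drew on all protein-coding genes, active in adipocytes or not. The excess therefore does not set these lists apart from active genes in general. Some genes are members of more than 1 list and many have peaks in both depots, so the pairs are not independent.

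**Figure D3:**
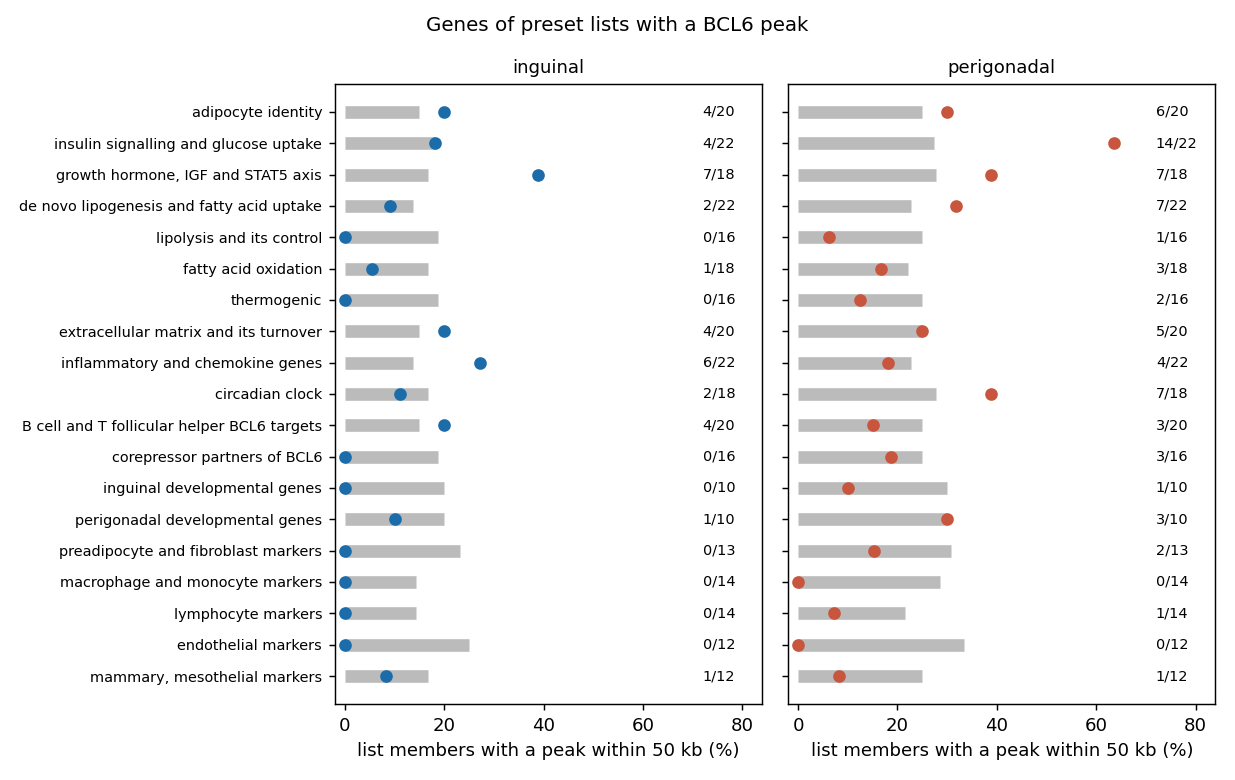
Percent of the members of each gene list with a BCL6 peak within 50 kb (x axis), for the inguinal (left) and perigonadal (right) list, with the counts at the right edge of each panel. Points are the observed shares and grey bars span from 2.5% to 97.5% of 10000 matched random lists; the growth hormone list lies right of the bar in both depots with 7 of 18 members, and the insulin list in perigonadal fat with 14 of 22.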

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

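The length test of the insulin list was set before its result was seen; the other tests in this part were chosen afterwards. Annotated repeats, which no comparison above used, held 21.1% of inguinal and 24.0% of perigonadal peaks. The share of repeats at random positions was not computed, so these values do not show whether peaks gather in repeats. The inguinal peak in a satellite repeat on chromosome X scored 37.6 and was the tallest of its list without a partner. Among peaks of up to 12 tags without a partner, 27.6% of inguinal and 28.3% of perigonadal peaks lay in repeats. Among shared peaks of up to 12 tags 13 of 72 and 15 of 94 did. Among peaks of more than 12 tags the shares were 16.9% and 11.9% without a partner and 9.86% and 11.8% with one.

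Most peaks had no partner in the other depot, 71.5% of the inguinal and 87.2% of the perigonadal list. Peaks near the calling limit may account for part of this. Height cannot settle how much, because weaker sites of a single depot would also lack a partner more often. Of peaks with more than 12 tags, 302 of 738 inguinal and 536 of 950 perigonadal ones had no partner. In the tallest part of each list 77.1% and 42.2% of peaks had a partner, and in the lowest 4.92% and 2.12%. Of peaks with more than 30 tags, 7 inguinal and 19 perigonadal ones had none. A difference between the depots, the libraries or the limits used for calling stays open for all peaks without a partner. Each depot had 1 library.

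The number of insulin signalling genes with a perigonadal peak, 14 of 22, was weighed against 3 explanations. With 1785 peaks the count fell from 14 to 8, so the count itself varies with the length of the list. Those 8 members still exceeded 100% of random lists, which had a median of 1. The random lists were scored on the same shortened list and so allow for its length at any setting. This test therefore cannot say how much of the 14 goes with length. An even scatter of low peaks over gene territory is argued against. The unshared peaks of up to 12 tags alone gave 11 members, more than in 100% of random lists, which had a median of 2. The list was picked from these same peaks. Random lists matched on territory alone cannot show whether low background peaks gather at active genes. A preference for any gene active in adipocytes stays open, since the other adipocyte lists went both ways. The same low peaks put the identity list (5 members, 98.7%) and the lipogenesis list (5 members, 97.8%) past the limit, but not the oxidation list (3 members, 88.8%) or the lipolysis list (0 members). Pooled over these 4 lists and not matched on territory, 21.4% of 70 members outside the insulin list had any perigonadal peak, against 63.6% of the insulin list.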

How the results depend on the processing

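Of 271 alternative values, 230 lay within the interval of the reported share, within 1.5 times the reported count or on the same side of the limit for lists. Of the 271, 168 belong to lists that were already under the limit. Outside the lists, 16 values left these bounds. Values within these bounds still moved: genes with a peak at any distance numbered 1346 and 2689, and peaks outside repeats 1409 and 3005. The alternatives with a limit of more than 12 tags, without repeats, with shared peaks only, with gene ends and with protein-coding promoters only were chosen after the data were seen. Peak numbers fell to 738 inguinal and 950 perigonadal with more than 12 tags, and the shares with a partner then were 51.2% and 39.8%. They were 48.3% and 21.8% in the taller 50% of each list, where fewer low peaks enter by construction, as with more than 12 tags. With lists of equal number the share was 25.9% on both sides. Only low perigonadal peaks were dropped there, so the inguinal share fell from 28.5%. Without the tallest 1% of shared peaks the correlation was 0.71. Promoter shares were 16.6% and 17.3% within 5 kb, and 8.97% and 7.89% at 1 kb in the taller 50% of each list. Genes with a peak within 10 kb numbered 396 and 872, and perigonadal genes with lists of equal number 958.

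The growth hormone list in both depots and the perigonadal insulin list were past the limit under every alternative run. The other 7 fell under it in 15 of their alternatives; the cause was not tested. With more than 12 tags these were inguinal identity (66.5%), inflammatory (67.1%) and B cell target genes (64.3%) and perigonadal identity (58.9%) and lipogenesis genes (54.0%). With shared peaks only they were inguinal identity (74.6%) and B cell target genes (96.1%) and perigonadal identity (74.6%), lipogenesis (72.2%) and clock genes (76.0%). Within 10 kb they were inguinal matrix (66.3%) and perigonadal lipogenesis genes (76.0%). With gene ends they were inguinal B cell targets (96.2%) and perigonadal clock genes (93.5%), and with lists of equal number perigonadal identity genes (75.8%). Of 168 alternatives for the 28 lists under the limit, 10 passed it. Inguinal insulin genes did so with unmatched random lists (98.7%), shared peaks (99.2%) and more than 12 tags (98.0%). Perigonadal matrix genes did so with equal lists (97.8%), gene ends (99.4%), shared peaks (99.5%) and more than 12 tags (99.7%). The others were inguinal lipogenesis (98.5%) and perigonadal corepressor genes (98.8%) with gene ends, and perigonadal inflammatory genes with shared peaks (99.6%). Alternatives by fold over input, by any start site and for the motif were not run. No paired analysis was possible because each depot had 1 library. Depth limits the low peaks most: at 10 tags the Poisson interval spans 4.80 to 18.4 tags.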

Other observations

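The tests in this part were chosen after the values were seen, as were the genes named. Of 12 Cxcl genes, chemokine ligands of the CXC class, 4 had an inguinal and 6 a perigonadal peak, and Cxcl5, Cxcl9 and Cxcl10 had shared ones. The perigonadal peaks rested on 8 to 11 tags each. Only Cxcl9 had an inguinal peak of more than 12 tags, with 16. Cxcl5 and Cxcl10 are also members of the inflammatory list. Among single genes, the promoter of Gbp7, an interferon-induced guanylate-binding protein gene, scored 40.6 in inguinal and 42.3 in perigonadal fat at chromosome 3:142530110-142530312. The promoter of its neighbour Gbp3 scored 21.1 in inguinal fat and had no perigonadal peak. A shared intergenic peak 34.5 kb from Socs5, a relative of Socs2, scored 24.1 and 22.0.

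A shared peak 108.8 kb upstream of Ptpn1, too far to count for the insulin list, scored 42.1 and 68.8 at chromosome 2:167823448-167823650, and one 35.2 kb upstream of Ptpn4 scored 37.6 and 63.5. In intron 2 of Esr1, the oestrogen receptor alpha gene, a shared peak scored 39.9 and 19.4, and 6 perigonadal peaks in all had Esr1 as their nearest gene. A site 22.0 kb upstream of Por, which encodes the electron donor of cytochrome P450 enzymes, scored 18.8 and 50.2. In the perigonadal list, 7 peaks each had Cd180 and Dapk1 as nearest gene, of which 0 and 1 were shared. Those of Cd180 lay 99.8 to 439.8 kb from its promoter, beyond the 50 kb limit, and those of Dapk1 6.24 to 115.8 kb.

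Whether the Cxcl genes stand out was tested among 347 gene families of at least 8 members with a common name. Shared peaks at 3 or more Cxcl genes occurred in 4 of 10000 random lists. Multiplied by the number of families this share is 0.139, so a chance result among many families remains a possible explanation for the shared peaks. The matching values were 0.0347 for all perigonadal and 0.382 for all inguinal peaks. The perigonadal value rests on 1 of 10000 random lists and on peaks of 8 to 11 tags. Random lists drew genes without regard to position, while several Cxcl genes lie close together on chromosome 5, so these values may be too low. Past the upper limit were 7 families in the inguinal and 6 in the perigonadal list, against 3.67 and 4.37 by chance. With shared peaks there were 3, against 3.05 by chance.

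Chromosome X held 14 inguinal and 30 perigonadal peaks, 0.784% and 0.758% of the lists, though 4.41% of protein-coding genes lie on it. Of these, 8 were shared. Counting peaks with at least the commonest number of tags, 11 in inguinal and 10 in perigonadal fat, left 11 and 25 on X. Fewer genes on X are not enough to explain this, since the autosomal number per gene predicts 65.9 and 148.6. A single copy of X may be a candidate explanation, as it would leave fewer sites past the limit. Autosomal peaks thinned to 50% of their tags predict 13.7 and 20.6 peaks on X by gene number, inside the Poisson intervals of 5.49 to 19.7 and 16.2 to 36.9. By chromosome length they predict 20.6 and 30.9, the first just above its interval. The sex of the mice is not given in the labels. Chromosome Y held 1 inguinal and 0 perigonadal peaks, too few to settle it. The hypothesis was found and tested on the same peaks.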
